A study of Mus musculus with 16 samples.

How the data were processed

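The deposited table holds TPM for 23982 entries in 16 libraries of whole mouse kidney, in 4 groups of 4 that were taken from the sample titles. The authors' TPM values had 2 decimals. Per the submitters' processing notes, Trim Galore, STAR 2.4.1d, HTSeq 0.6.1 and DESeq2 1.10.1 were used, with the builds GRCm38 and mm10; the role and order of each tool, the gene lengths behind the TPM, the annotation and the strand setting are not given in the sources used here. TPM sets each library to a fixed total, so a fall of abundant transcripts raises the values of the others, and it keeps no read depth: neither the depth per sample nor a counting interval can be given. Entries that share a symbol (94 of them) were summed, which left 23935 symbols; 26 identifiers read as calendar dates, the usual trace of a spreadsheet, and 5699 symbols were listed at 0 in every library. An exact 0 is given as listed at 0, with no fold against it. Gene positions were taken from GENCODE vM21, in which 97.4% of the symbols matched 1 gene.

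Genes with at least 1 TPM in at least 4 of the 16 libraries were tested (12960). Values were log2(TPM + 1), so that a fold change understates the change of genes with low values. A single limma model (limma 3.58.1, R 4.3.3, statmod 1.5.0) with 4 group means and 12 residual degrees of freedom gave each comparison, with empirical Bayes moderation (trend and robust) and Benjamini-Hochberg adjustment over all tested genes; a gene was called at an adjusted p under 0.05. In the text, rose, fell, higher and lower refer to calls at this threshold, TPM values are group means ± SD with n = 4, and all other tests are two-sided. Because TPM moved the median of all genes by more than 0.1 in the comparisons with cisplatin, counts after median-of-ratios scaling are given beside the main ones, and list medians are given relative to that of all genes.

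Before the data were examined, 48 gene lists (cell types, pathways, tissues that could be carried along, and signs of sample handling and RNA quality) were fixed; 42 had enough members for a set test. Lists were tested with camera with the preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 42 lists; list means per library were compared with exact permutation tests. Counts adjusted over the list alone use the p-values of its members only. The genes to name were also fixed by rule: per comparison the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 5 TPM, without predicted genes, pseudogenes and mitochondrially encoded genes; 2 to 4 members of each described list with the smallest adjusted p; and 16 genes always. Among the 12960 genes, the groups did not overlap for 50.8% in cisplatin against PBS. Chance gives 2.86% for 4 against 4 libraries.

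The returned share was computed on genes called in 2 PBS and 2 cisplatin libraries and measured in the other libraries of these groups. The procedure was tested on simulated data with 200 changed genes of 12960: for cisplatin against PBS 21.5%, 84.5% and 99.5% of genes changed 1.5-, 2- and 4-fold were recovered, and for NMN against NR 16%, 87% and 98%. Alternatives tried were limma without trend and robust, median-of-ratios and quantile scaling, removal of the mitochondrially encoded genes, a pseudocount of 0.1, a minimum of 5 TPM and no minimum, only the groups compared, array weights, a replicate block, and each replicate left out. Chosen after seeing the data were fits without the 3 libraries of lowest weight (PBS 1, cisplatin 1 and cisplatin 3) and without NR libraries 3 and 4. Also chosen after seeing the data was a test of the position of 30 lists between PBS and cisplatin against the spread between the libraries of all 3 groups. It is given without a p-value, as a distance from genes changed in the same direction and its SE. Count models did not apply to TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).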

Results

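RNA of whole kidneys from wild-type mice was sequenced in 16 samples, 4 in each of 4 groups: PBS, cisplatin, cisplatin with NMN, and cisplatin with NR. Cisplatin is a platinum drug that crosslinks DNA and injures the kidney tubule. NMN (nicotinamide mononucleotide) and NR (nicotinamide riboside) are precursors of NAD, a cofactor of metabolism and the substrate of sirtuins and PARPs, and NMN is the phosphorylated form of NR. Per the labels, the precursors were injected before cisplatin and the kidneys were collected 3 days after it; the doses are not given in the sources used here. The samples are separate entries of 1 group each, but no label says that they came from separate animals, so the p-values measure the spread between these samples, which may be technical. The comparisons ask what cisplatin changed, what NMN and NR changed beside cisplatin alone, how far the libraries with a precursor lay from PBS, and whether NMN and NR differed.

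The values are TPM, transcript abundances scaled to a fixed total per library. They keep no read depth, so the depth behind each value is unknown. The listed TPM summed to between 860428 and 903678 per library, and 11535 to 12549 genes reached 1 TPM. The 13 mitochondrially encoded mRNAs made up 28.6% ± 4.17 of the listed TPM with PBS, 16.6% ± 0.845 with cisplatin, 26.0% ± 2.63 with NMN and 26.4% ± 3.6 with NR (SD, n = 4 each). Ribosomal protein genes made up 3.38% ± 0.31, 8.73% ± 0.436, 4.56% ± 0.466 and 4.70% ± 0.6 in the same order. The first principal component held 63.5% of the variance and set the cisplatin libraries apart, and the second held 5.7%. The median correlation between libraries across genes was 0.834 for PBS against cisplatin, 0.96 for PBS against NMN, 0.954 for PBS against NR and 0.977 for NMN against NR, where genes are not independent replicates.

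**Figure D1:**
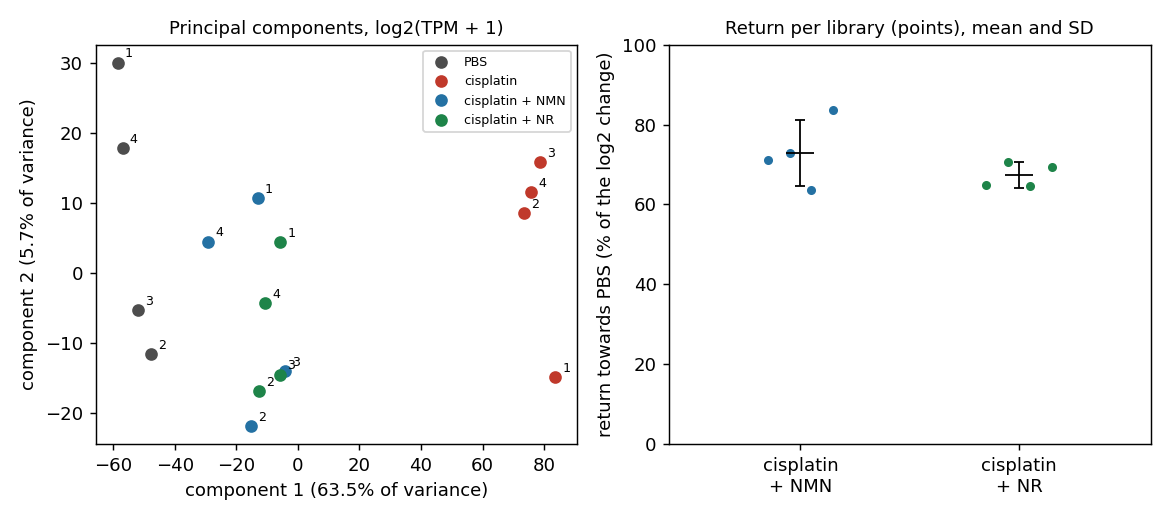
Left: the 4 groups on the first and second principal component of log2(TPM + 1), with the replicate number beside each library. Right: percent of the cisplatin change, on the log2 scale, that was absent in each library with NMN or NR, as points with the mean and SD in black; the means were 72.8% with NMN and 67.4% with NR.

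Cisplatin raised markers of tubular injury and lowered transporters of the proximal tubule. Havcr1, the kidney injury molecule of damaged proximal tubules, rose from 0.63 ± 0.691 to 1204 ± 60.1 TPM. Lcn2, a secreted iron-siderophore carrier, rose from 1.72 ± 1.4 to 1422 ± 163 TPM (SD, n = 4; log2 changes 9.61 and 9.16). Cdkn1a, the cell cycle inhibitor p21, rose from 2.59 ± 1.02 to 783 ± 85.7 TPM, and the keratin gene Krt20 from 0.03 ± 0.0424 to 853 ± 102 TPM. The other large rises were Sprr1a and Sprr2f, genes of the cornified envelope, S100a6, which encodes a calcium-binding protein, the AP-1 factor Fosl1, Crct1, and the acute phase gene Saa1. Crct1 and Saa1 were listed at 0 in every PBS library and reached 118 ± 7.43 and 84.3 ± 27.2 TPM with cisplatin. Slc34a1, the phosphate transporter of the proximal tubule, fell from 3255 ± 150 to 73.6 ± 10.7 TPM, and Inmt, an N-methyltransferase gene, from 1294 ± 37.2 to 20.7 ± 4.71 TPM. Nat8f6, Slc7a13, Ugt2b38 and Slc22a28 were also among the 10 largest falls, with log2 changes of -6.64 to -5.71. The remaining 4 were globin genes, described with the blood cells. In GRCm38, Havcr1 lies on chromosome 11 from 46735080 to 46779578, Lcn2 on chromosome 2 from 32384633 to 32388252, Cdkn1a on chromosome 17 from 29090976 to 29100727 and Slc34a1 on chromosome 13 from 55398187 to 55415592.

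**Figure D2:**
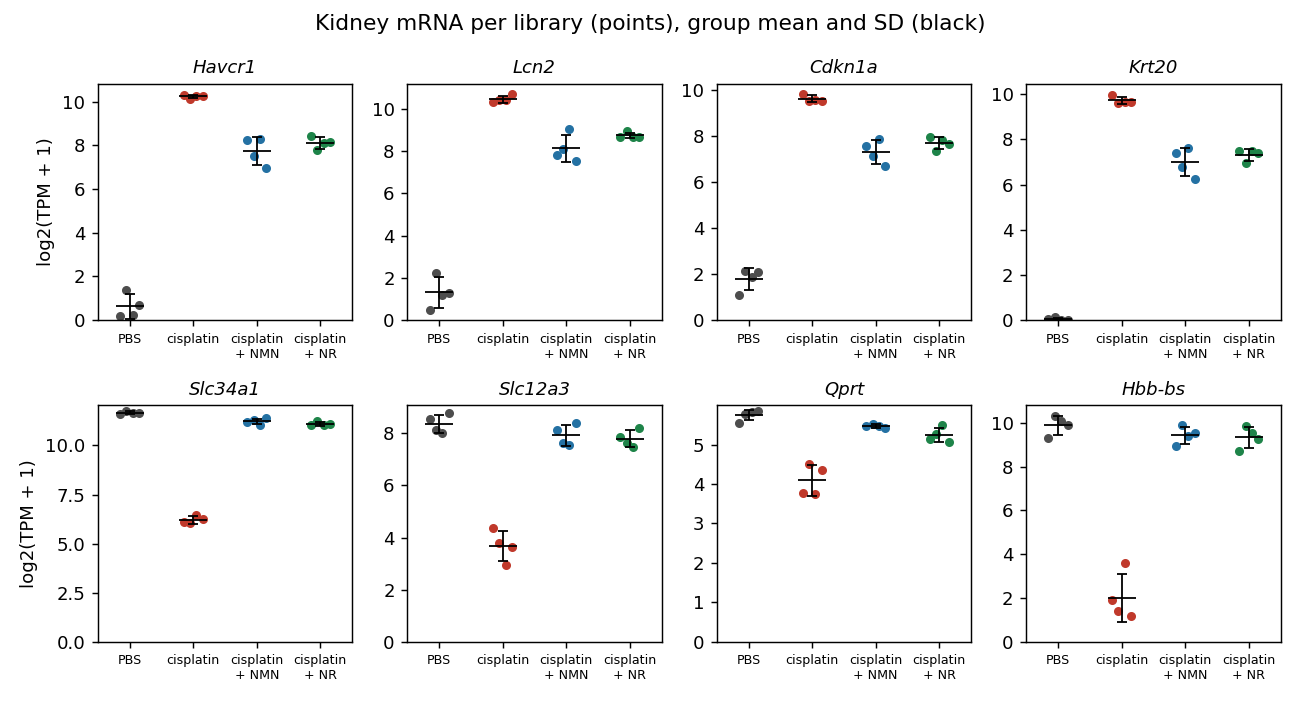
Kidney mRNA on the log2(TPM + 1) scale for 8 genes, with 1 point per library and the group mean and SD in black. The PBS and cisplatin libraries did not overlap for any of these genes, and the means with NMN and NR lay between theirs: Havcr1 averaged 228 TPM with NMN and 278 with NR.

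All 25 tested injury markers rose with cisplatin, as did 24 of 25 targets of the DNA damage factor p53. Among these were the stress cytokine gene Gdf15 (4.8 ± 1.58 to 384 ± 19.4 TPM) and Phlda3 (4.7 ± 1.18 to 250 ± 7.39 TPM). Their median log2 changes lay 3.86 and 2.81 above the median of all genes (camera with a preset correlation, adjusted p = 4.85e-15 and 9.83e-13; adjusted p = 0.221 for each with an estimated correlation). Of 30 proximal tubule genes 29 fell and 1 rose, including the organic anion transporter Slc22a8 (177 ± 18.3 to 6.24 ± 0.676 TPM) and the glucose transporter Slc5a2 (300 ± 28.1 to 29.9 ± 2.53 TPM). The median change of this list lay -3.42 from that of all genes, and the call held with an estimated correlation (adjusted p = 0.0432), which was so for no other list in this comparison. In the distal convoluted tubule list 9 of 11 genes fell and 1 rose (10 fell when adjusted over the list alone), with Slc12a3, the thiazide-sensitive cotransporter, at 336 ± 84 against 12.6 ± 5.2 TPM. In the thick ascending limb list 7 of 12 fell, including the growth factor gene Egf and the tight junction gene Cldn10, whereas Umod measured 568 ± 298 with PBS and 401 ± 194 TPM with cisplatin (adjusted p = 0.359). Of 12 genes of intercalated cells 8 fell, among them the proton pump subunit gene Atp6v1b1. Of 12 podocyte genes 10 fell, among them the slit diaphragm gene Nphs1, and the list mean was higher in cisplatin library 1 (3.043) than in the other 3 (1.611 to 1.68). These 4 lists were called lower by camera (adjusted p from 2.6e-07 to 0.00035; adjusted p from 0.221 to 0.279 with an estimated correlation). Principal cell genes went both ways: 4 of 11 rose, with the water channel gene Aqp2 at 168 ± 22.6 and 384 ± 35.9 TPM. A further 3 fell (4 when adjusted over the list alone), and the list was not called (adjusted p = 0.548).

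Genes of several non-epithelial cell types were also lower with cisplatin. Of 14 endothelial genes 11 fell, including Plvap and the VEGF receptor gene Kdr. Of 13 genes of fibroblasts and pericytes 9 fell and 1 rose (10 fell when adjusted over the list alone), with renin (Ren1) at 106 ± 37.6 and 20.4 ± 27.3 TPM. Cisplatin library 1 held 61.44 TPM of Ren1 and the other 3 held 5.82 to 7.53. Of 7 dendritic cell genes 5 fell, led by the MHC class II genes H2-Aa (78.4 ± 30.8 to 7.05 ± 5.24 TPM) and Cd74 (220 ± 88.6 to 31.3 ± 14.2 TPM). Camera called these 3 lists lower (adjusted p = 9.24e-06, 0.00205 and 0.000358), with adjusted p of 0.279, 0.432 and 0.279 with an estimated correlation. Among 15 tested macrophage and monocyte genes Cd68 and Cd14 rose while the growth factor receptor gene Csf1r and 2 others fell. The list's median change was below 0 (-0.20) and its mean above (0.27), and it was not called (adjusted p = 0.333). The 4 tested neutrophil genes were not called (limma), and none had an unadjusted p under 0.05 (camera adjusted p = 0.928). Both tested genes of B and plasma cells, Cd79a and Mzb1, rose, and Lck, the only T cell gene that passed the filter on low values, measured 0.66 ± 0.267 and 0.88 ± 0.747 TPM (adjusted p = 0.748). The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were 4 of the 10 largest falls, with Hbb-bs at 985 ± 270 and 4.17 ± 4.66 TPM. All 6 tested red blood cell genes fell (camera adjusted p = 3.22e-07; adjusted p = 0.0772 with an estimated correlation). Of 7 adipose genes 6 rose (7 when adjusted over the list alone), the lipid droplet gene Cidec among them, though camera did not call the list (adjusted p = 0.122). The summed TPM of 8 adipose genes was 393, 210, 403 and 224 in the cisplatin libraries and between 25.2 and 124 in the PBS libraries. Some of these genes, such as the globins, Ugt2b38 and Nat8f6, belong to families of near-identical copies, and the split of reads among copies is uncertain; this also holds for the Saa, Rnu3b, Gsta and Cyp4a genes named elsewhere.

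Inflammatory and antiviral genes rose with cisplatin. Of 21 tested cytokines and chemokines 17 rose, including the neutrophil attractants Cxcl1 (1.26 ± 1.04 to 101 ± 7.69 TPM) and Cxcl2, the cytokine gene Lif and the monocyte attractant Ccl2 (0.51 ± 0.486 to 6.79 ± 2.62 TPM). Of 38 interferon-stimulated genes 34 rose, including Irf7, which encodes an interferon regulatory factor (6.6 ± 1.62 to 73 ± 9.27 TPM), and Isg15. In the nucleic acid sensing list 17 of 21 rose, among them the NF-kB subunit genes Nfkb2 and Rela. The RNA sensor genes Ddx58, which encodes RIG-I (5.71 ± 1.31 to 21.3 ± 4.07 TPM), and Ifih1 (2.6 ± 0.549 to 6.47 ± 1.5 TPM), their adaptor gene Mavs (23.3 ± 3.78 to 34.9 ± 4.54 TPM) and Tmem173, which encodes the DNA-sensing adaptor STING (2.01 ± 0.912 to 10.2 ± 4.71 TPM), all rose (adjusted p from 1.17e-06 to 0.00148). Camera called these 3 lists higher (adjusted p = 1.2e-05, 2.71e-07 and 0.000912), with adjusted p of 0.255, 0.279 and 0.279 with an estimated correlation, and their counts were the same when adjusted over the list alone. After median-of-ratios scaling, in which the median change of all genes was near 0, 32 interferon-stimulated and 14 sensing genes rose. Tnf, Il6 and Mb21d1, fixed among the genes to name, did not pass the filter on low values.

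Genes of NAD synthesis and of mitochondrial metabolism were lower with cisplatin, in the same libraries in which proximal tubule genes were lower (29 of 30, median change -3.42 from that of all genes). The median change from that of all genes was -1.39 for NAD synthesis, -1.20 for mitochondrially encoded mRNAs, -0.72 for oxidative phosphorylation, -1.03 for the citric acid cycle and -0.58 for fatty acid oxidation. Of 16 NAD synthesis genes 12 fell and 1 rose (2 rose when adjusted over the list alone), among them Kmo, Afmid, Haao and Qprt, which act on the route from tryptophan. Qprt fell from 53 ± 4.86 to 16.6 ± 4.78 TPM and the NR kinase gene Nmrk1 from 53.6 ± 6.43 to 29.4 ± 2.67 TPM. Nampt, the gene of the salvage enzyme, measured 28 ± 4.24 and 32.3 ± 5.71 TPM (adjusted p = 0.31). Of 22 genes of NAD consumption and nicotinamide disposal 11 rose and 3 fell (7 fell after median-of-ratios scaling). Bst1, which encodes an NAD-cleaving enzyme, rose, and Acmsd and the mitochondrial sirtuin gene Sirt3 fell, and the list was not called (adjusted p = 0.931). Of 13 mitochondrially encoded mRNAs 10 fell, of 38 nuclear genes of oxidative phosphorylation 27, of 17 genes of the citric acid cycle 14 (15 when adjusted over the list alone), and of 32 fatty acid oxidation genes 17 fell and 7 rose. After median-of-ratios scaling the falls were 13, 31, 17 and 20. Examples were the complex I gene Ndufs1 (102 ± 10.9 to 39.2 ± 7.41 TPM), Idh2 (281 ± 34.6 to 71.5 ± 12.4 TPM) and Hadh (223 ± 16.2 to 72.2 ± 12.4 TPM), whereas Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose. The NAD synthesis list and these 4 lists were called lower by camera (adjusted p from 1.81e-08 to 0.000346), with adjusted p from 0.221 to 0.291 with an estimated correlation.

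Genes of stress responses rose with cisplatin, and so did lists fixed as signs of sample handling (immediate early genes) and of RNA quality (ribosomal protein genes). Targets of the oxidative stress factor NRF2 rose in 18 of 23 cases and fell in 2, led by the metallothionein gene Mt2 (143 ± 30.5 to 6091 ± 1070 TPM) and the haem oxygenase gene Hmox1. Of 27 genes of the integrated stress response 21 rose and 2 fell, with Atf4 at 60.9 ± 8.46 and 180 ± 9.75 TPM. Of 18 immediate early genes 16 rose and 1 fell, among them Egr1 and Junb. Of 22 cell cycle genes 15 rose, including Rrm2 and Pcna, which act in DNA synthesis. All 25 ribosomal protein genes rose, with Rplp0 at 643 ± 74.2 and 2168 ± 73.7 TPM. Camera called these 5 lists higher (adjusted p from 1.11e-10 to 0.0255), with adjusted p from 0.255 to 0.286 with an estimated correlation. Over all genes, 7693 of 12960 changed with cisplatin (limma, adjusted p under 0.05), 5278 higher and 2415 lower, of which 2381 and 1178 changed at least 2-fold. The median log2 change of all genes was 0.27 in TPM and -0.001 after median-of-ratios scaling, under which 3787 genes were higher and 3709 lower. The share of higher calls went from 68.6% to 50.5%. Camera called 27 of 42 lists, and 1 with an estimated correlation.

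**Figure D3:**
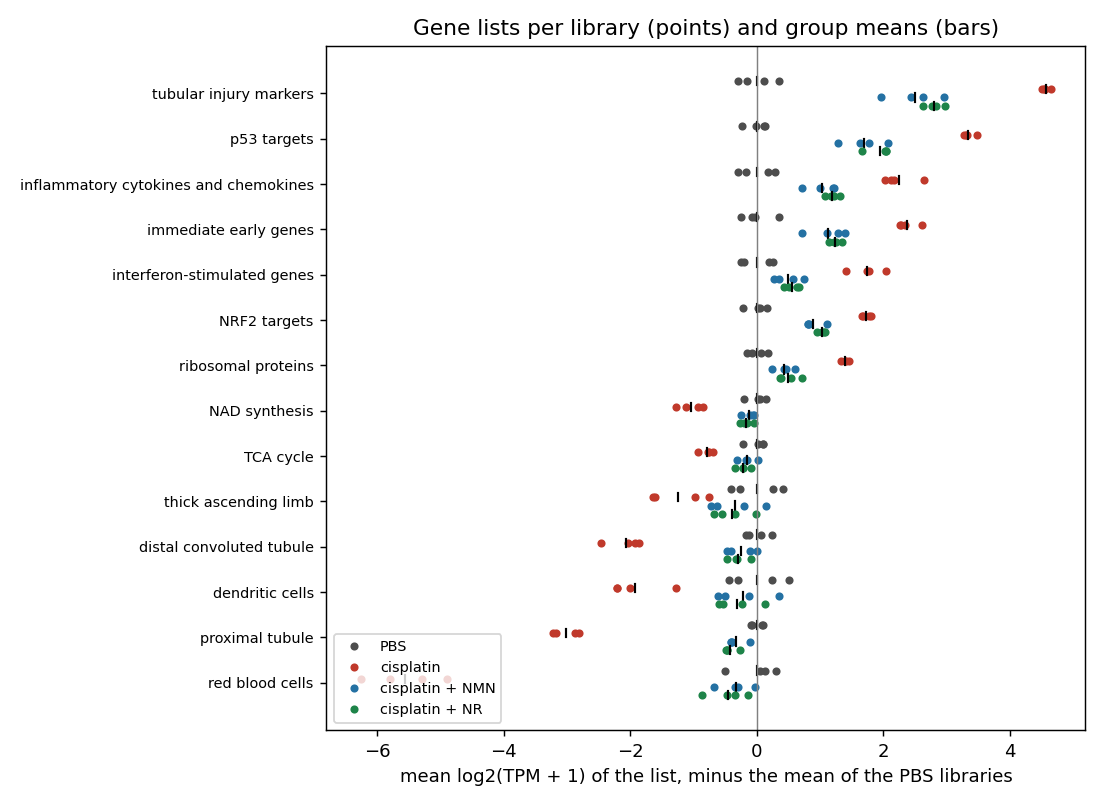
Mean log2(TPM + 1) of 14 gene lists in each library, minus the mean of the PBS libraries; points are libraries, colours are groups and black bars are group means. Injury markers averaged 4.56 above PBS with cisplatin, 2.5 with NMN and 2.8 with NR, and proximal tubule genes -3.02, -0.33 and -0.43.

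With NMN before cisplatin, injury genes were lower and tubule genes higher than with cisplatin alone. Havcr1 fell to 228 ± 91.6 TPM, Lcn2 to 305 ± 155 TPM and Cdkn1a to 165 ± 56.9 TPM (log2 changes -2.49, -2.33 and -2.30), and Slc34a1 rose to 2400 ± 239 TPM. The 10 largest rises over cisplatin alone were the same 10 genes as the largest falls with cisplatin, with Hbb-bs at 713 ± 187 and Inmt at 973 ± 94.9 TPM. The largest falls included 4 copies of the small nucleolar RNA gene Rnu3b with identical values, the haemoglobin scavenger Hp (67.9 ± 20.2 to 2.62 ± 2.38 TPM), the telomerase gene Tert, the urea transporter gene Slc14a2, Lrg1, Serpina10 and the decoy receptor gene Tnfrsf23. All 25 injury markers and 24 of 25 p53 targets fell, 28 of 30 proximal tubule genes rose and 1 fell, and 10 of 11 distal convoluted tubule genes rose and 1 fell. Of the cytokines 17 of 21 fell, of interferon-stimulated genes 31 of 38 (34 when adjusted over the list alone) and of sensing genes 14 of 21. Ddx58 fell to 8.37 ± 2.99, Tmem173 to 3.36 ± 1.45 and Ccl2 to 2.94 ± 1.15 TPM, though Ccl2 was not called with a pseudocount of 0.1 (adjusted p = 0.0902). Beside the 28 of 30 proximal tubule genes, 12 of 16 NAD synthesis genes rose and 1 fell, with Qprt at 43.5 ± 1.35 and Nmrk1 at 49.7 ± 6.35 TPM. Of mitochondrially encoded mRNAs 10 of 13 rose. Of immediate early genes, fixed as a sign of sample handling, 15 of 18 fell (16 fell and 1 rose when adjusted over the list alone). Among endothelial genes 11 of 14 rose, among podocyte genes 8 of 12 (9 when adjusted over the list alone) and among dendritic cell genes 5 of 7. All 25 ribosomal protein genes fell and all 6 red blood cell genes rose. Camera called all of these lists (adjusted p at most 0.00161). Of 7 adipose genes 5 fell (7 when adjusted over the list alone), and this list was not called (adjusted p = 0.0503, and 0.543 with an estimated correlation). With an estimated correlation the proximal tubule and red blood cell calls held (adjusted p = 0.0204 and 0.0348), and the others had an adjusted p from 0.2 to 0.309. Umod and Nampt measured 472 ± 234 and 29.9 ± 5.36 TPM and were not called (adjusted p = 0.67 and 0.603). Over all genes, 6359 changed (limma), 1954 higher and 4405 lower. After median-of-ratios scaling, which moved the median change from -0.23 to -0.015, 2909 were higher and 3022 lower. The share of higher calls went from 30.7% to 49%.

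With NR before cisplatin, injury genes were also lower and tubule genes higher than with cisplatin alone. Havcr1 fell to 278 ± 49.1 TPM, Lcn2 to 431 ± 43.6 TPM and Cdkn1a to 209 ± 38.1 TPM (log2 changes -2.13, -1.72 and -1.92), and Slc34a1 rose to 2196 ± 180 TPM. The 10 largest rises over cisplatin alone were again the 10 largest falls with cisplatin. The largest falls shared 5 genes with those under NMN, the Rnu3b copies and Tert, and added S100a6 (2899 ± 453 to 353 ± 73.2 TPM), Sh2d5, the autophagy gene Atg9b and the neuropeptide gene Calcb, among others. All 25 injury markers and 24 of 25 p53 targets fell, 28 of 30 proximal tubule genes rose and 1 fell, and 9 of 11 distal convoluted tubule genes rose. Of the cytokines 16 of 21 fell, of interferon-stimulated genes 30 of 38 (31 when adjusted over the list alone) and of sensing genes 14 of 21. Ddx58 fell to 11.5 ± 1.43 and Ccl2 to 2.91 ± 0.165 TPM, while Tmem173 measured 6.82 ± 1.43 TPM (adjusted p = 0.233), and Ccl2 was again not called with a pseudocount of 0.1 (adjusted p = 0.111). Beside the 28 of 30 proximal tubule genes, 12 of 16 NAD synthesis genes rose and 1 fell, with Qprt at 37.1 ± 5.15 and Nmrk1 at 44.9 ± 7.06 TPM. Of mitochondrially encoded mRNAs 11 of 13 rose. Of immediate early genes, fixed as a sign of sample handling, 15 of 18 fell (15 fell and 1 rose when adjusted over the list alone). Among endothelial genes 11 of 14 rose, among podocyte genes 8 of 12 and among dendritic cell genes 5 of 7. All 25 ribosomal protein genes fell and all 6 red blood cell genes rose. Of 7 adipose genes 0 were called (limma; 1 with an unadjusted p under 0.05), and the summed TPM of the list was 23.2, 110, 393 and 245 in NR libraries 1 to 4, against 30, 104, 51.7 and 25.6 with NMN. Camera called these lists except the adipose one (adjusted p at most 0.00178, and 0.611 for adipose genes). With an estimated correlation the proximal tubule and red blood cell calls held (adjusted p = 0.0177 and 0.0307), and the other calls had an adjusted p from 0.183 to 0.3. Umod and Nampt measured 398 ± 186 and 30.5 ± 4.17 TPM (adjusted p = 0.982 and 0.736). Over all genes, 6044 changed (limma), 1870 higher and 4174 lower. After median-of-ratios scaling, which moved the median change from -0.20 to -0.017, 2786 were higher and 2867 lower. The share of higher calls went from 30.9% to 49.3%. The mean of NMN and NR differed from cisplatin in 7031 genes, 2161 higher and 4870 lower (3192 and 3348 after median-of-ratios scaling, median change from -0.21 to -0.018, 30.7% and 48.8% higher). Hbb-bs was again the largest rise and the Rnu3b copies were the largest falls.

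Set against PBS, the libraries with NMN still held injury transcripts. Havcr1, Sprr1a, Krt20, Lcn2 and Cdkn1a were the 5 largest rises, with log2 changes from 7.12 to 5.51. The glutathione transferase gene Gsta1 (1.16 ± 1.1 to 45.4 ± 8.88 TPM), Gdf15 and S100a6 were among the 10, and Crct1 and Sprr2g, also among them, were listed at 0 with PBS. Of 25 injury markers 22 were higher, and of 25 p53 targets 22 (23 when adjusted over the list alone). These 2 list calls held with an estimated correlation (adjusted p = 0.032 each). Immediate early genes were higher in 13 of 18 cases (14 when adjusted over the list alone) and cytokines in 10 of 21. NRF2 targets were higher in 9 of 23 (14 when adjusted over the list alone), ribosomal proteins in 14 of 25 (24 when adjusted over the list alone; 10 after median-of-ratios scaling) and interferon-stimulated genes in 8 of 38 (11 when adjusted over the list alone). Camera called these 5 lists (adjusted p at most 4.56e-05; adjusted p from 0.0951 to 0.501 with an estimated correlation). Proximal tubule genes were called lower as a list (median -0.40 from all genes; camera adjusted p = 9.92e-13; adjusted p = 0.0951 with an estimated correlation), with Slc34a1 and Slc22a8 lower among 30 (7 lower and 1 higher when adjusted over the list alone). The other 8 of the 10 largest falls were Emx1, which fell by 0.62 on the log2 scale, and, by less, Susd2, Cpq, Slc22a18, the lipoprotein lipase gene Lpl, the carbonic anhydrase gene Car4, Tmem27 and the argininosuccinate synthase gene Ass1. Each of these 10 calls ended when a single library was left out. For Slc34a1 this was NMN library 3 (log2 change -0.38, adjusted p = 0.0656), and for the other 9 it was any 1 of 4 to 7 libraries, with a highest adjusted p from 0.0691 (Emx1) to 0.211 (Slc22a8). Every PBS library and NMN libraries 1 to 3 ended at least 1 of these calls. Of 16 NAD synthesis genes 0 were called by limma and 2 had an unadjusted p under 0.05 (Qprt adjusted p = 0.424, Nmrk1 adjusted p = 0.768). Ddx58 and Tmem173 were not (adjusted p = 0.292 and 0.42), whereas Ccl2 was higher (adjusted p = 0.00252). In all 778 genes differed from PBS (limma), 763 higher and 15 lower. After median-of-ratios scaling 738 were higher and 96 lower, or 88.5% instead of 98.1% higher. Without NMN replicate 3 the count was 511.

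The libraries with NR differed from PBS in 1296 genes (limma), 1139 higher and 157 lower, or 1047 and 486 after median-of-ratios scaling (68.3% instead of 87.9% higher). Without NR libraries 3 and 4, which hold adipose transcripts and were left out after seeing the data, the count was 698. Havcr1, Lcn2, Sprr1a, Krt20 and Cdkn1a were again the 5 largest rises, with log2 changes from 7.49 to 5.90, and 9 of the 10 largest rises were those under NMN. Injury markers were higher in 22 of 25 cases (24 when adjusted over the list alone) and p53 targets in 24 of 25, with an adjusted p of 0.0369 for each with an estimated correlation. Immediate early genes were higher in 13 of 18 cases (15 when adjusted over the list alone) and cytokines in 11 of 21 (12 when adjusted over the list alone). NRF2 targets were higher in 15 of 23, ribosomal proteins in 21 of 25 (24 when adjusted over the list alone; 13 after median-of-ratios scaling) and interferon-stimulated genes in 8 of 38 (13 when adjusted over the list alone). Camera called these 5 lists (adjusted p at most 2.55e-05; adjusted p from 0.0944 to 0.455 with an estimated correlation). Of 30 proximal tubule genes 12 were lower and 1 higher (22 lower when adjusted over the list alone; camera adjusted p = 1.92e-14; adjusted p = 0.0944 with an estimated correlation). Slc34a1, Cpq, the steroid dehydrogenase gene Hsd3b2, the aspartoacylase gene Aspa and the carbonic anhydrase gene Car14 were lower, the last 4 among the 10 largest falls with Pzp and Apoh. Qprt, Ddx58, Tmem173 and Ccl2 were called against PBS (adjusted p = 0.049, 0.00753, 0.004 and 0.00154), Qprt lower and the others higher, and Nmrk1 was not (adjusted p = 0.268, and 0.0474 after median-of-ratios scaling). The calls of Qprt, Aspa, Car14 and Pzp ended when any 1 of 4 to 7 libraries was left out, with a highest adjusted p of 0.131, 0.0752, 0.121 and 0.0852, and each of the 8 libraries ended at least 1 of them. Of 7 adipose genes 1 was higher (2 when adjusted over the list alone; camera adjusted p = 0.0157; adjusted p = 0.552 with an estimated correlation).

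NMN and NR were compared directly, at doses that are not given in the sources used here. No gene was called (limma, 0 of 12960), with 370 genes at an unadjusted p under 0.05 where 648 would be expected by chance. For 12071 genes (93.1%) the 95% interval of the difference lay within 2-fold of TPM + 1, a scale that understates differences of genes with low values. The log2 difference, NMN minus NR, was -0.37 for Havcr1 (95% interval -0.95 to 0.22) and -0.61 for Lcn2 (-1.26 to 0.04). For Cdkn1a it was -0.39 (-0.89 to 0.12), for Tmem173 -0.89 (-1.52 to -0.26) and for Slc34a1 0.13 (-0.10 to 0.35), and each of the 5 had an adjusted p of 1. Camera called 9 of 42 lists, with lower mean log2 values under NMN for injury markers (-0.30), p53 targets (-0.26), NRF2 targets (-0.14), ferroptosis and iron handling (-0.12), complement and acute phase (-0.29) and adipose genes (-1.45). Higher mean values under NMN were called for the proximal tubule (0.10), oxidative phosphorylation (0.09) and the citric acid cycle (0.06). With an estimated correlation none of the 9 was called (adjusted p = 0.881 each), and fry, which tests a list without setting it against other genes, called 0 (adjusted p = 0.904). No exact permutation p of a list mean between the 2 groups was below 0.05 among these 9 (0.143 for the smallest; 0.0286 is the smallest that 4 against 4 libraries can give). This permutation did not use the library numbers. Within numbers, the list mean differed in 1 direction in all 4 for 3 of the 9, higher with NMN for the proximal tubule and the citric acid cycle and lower for complement and acute phase (exact sign-flip p = 0.125 each, the smallest that 4 differences can give). The summed TPM of the adipose genes was 393 and 245 in NR libraries 3 and 4, and at most 110 in the other 6 libraries with a precursor.

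The share of the cisplatin change that was absent with a precursor was estimated on genes and libraries held apart: genes were chosen in 2 PBS and 2 cisplatin libraries and measured in the other 2 of each, over 36 such splits. NMN libraries had returned 72.7% of the log2 change (69.7% to 77.6% over the splits) and NR libraries 67.1% (64.3% to 72.6%). Genes that rose with cisplatin had returned less than genes that fell: 66.8% against 84.2% with NMN and 61.1% against 79.4% with NR, in all 36 splits for each. On the TPM scale this order was not kept, but the genes and the summary also differed. Medians were taken over genes changed at least 2-fold that averaged at least 5 TPM in PBS or cisplatin (median 3013.5 genes, against 5163). Genes that rose lay 19.5% of the way from PBS to cisplatin with NMN (15.2% to 23.6% over the splits) and 23.8% with NR (19.1% to 28.1%). Genes that fell lay at 26.1% (17.5% to 33.1%) and 34% (24.7% to 40.6%). Per library the mean was 72.8% ± 8.2 with NMN and 67.4% ± 3.1 with NR (SD, n = 4; two-sided exact permutation p = 0.257). Of 5278 genes higher with cisplatin, 4254 (80.6%) were called lower with NMN than with cisplatin and 4038 (76.5%) with NR. Of the same genes 760 (14.4%) and 1127 (21.4%) were still above PBS. Of 2415 genes lower with cisplatin, 1887 (78.1%) and 1793 (74.2%) were called higher with NMN and NR, and 15 and 156 were still below PBS. The cisplatin change and the change with NMN beside cisplatin correlated at -0.951 across genes, and with NR at -0.938. Unchanged groups simulated with the same shared libraries gave -0.502, and the cisplatin libraries split so that none is shared gave -0.89 and -0.876. The covariances were -0.891 and -0.829 against a simulated -0.0262. NMN and NR shared 1684 genes higher and 3780 lower than the same 4 cisplatin libraries, and 702 genes higher and 14 lower than the same 4 PBS libraries. Their changes against cisplatin correlated at 0.966 (0.497 simulated, 0.883 with the cisplatin libraries split; covariance 0.628 against a simulated 0.0258). Those against PBS did so at 0.895 (0.497 simulated, 0.708 split; covariance 0.183 against 0.0258).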

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

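Tests of RNA carried over from cisplatin or PBS libraries, of list positions against the spread between libraries and of the TPM total were chosen after the result was seen. Within each group of 4 libraries, Dixon's test asked whether the highest or lowest library lay apart from the other 3, and chance sets about 1 in 20 groups apart. Of 771 groups tested, 40 did: 34 of 577 for named genes, 6 of 168 for list means, 0 of 24 for measures of the libraries and 0 of 2 for the returned share. Of the 40, cisplatin library 1 held 7 and NMN library 2 held 5, the latter including 4 copies of Rnu3b that share their values. As mean log2(TPM + 1) of a list, p53 targets were lower in NR 2 (4.288 against 4.651 to 4.675) and DNA repair genes in cisplatin 3 (3.394 against 3.516 to 3.538). Proximal tubule genes were higher in NMN 4 (8.832 against 8.53 to 8.548) and in NR 4 (8.666 against 8.453 to 8.474), podocyte genes in cisplatin 1 (3.043 against 1.611 to 1.68), and NRF2 targets in NMN 3 (6.971 against 6.662 to 6.677).

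Above the other 3 libraries of its group, in TPM, lay Apoh in cisplatin 4 (3.56 against 1.06 to 1.34), Atp6v1b1 in NMN 2 (80 against 53.03 to 56.22), Bst1 in PBS 3 (3.2 against 0.87 to 1.12), Cxcl2 in PBS 3 (0.57 against 0), Egr1 in cisplatin 1 (77.04 against 67.57 to 68.06) and Fosl1 in PBS 4 (0.28 against 0). In the same way high were Gsta1 in cisplatin 4 (157 against 124.2 to 127.7), Krt20 in cisplatin 1 (1006 against 788.2 to 812.8), Lcn2 in NR 2 (495.9 against 405.1 to 410.8), Pcna in NMN 3 (38.89 against 30.68 to 31.11), Pzp in cisplatin 2 (1.47 against 0.07 to 0.19) and Ren1 in cisplatin 1 (61.44 against 5.82 to 7.53). Also high were each of the 4 Rnu3b copies in NMN 2 (15.64 against 0), Serpina10 in NMN 3 (10.65 against 3.39 to 3.98), Slc14a2 in PBS 3 (0.08 against 0), Slc14a2 in NR 2 (10.35 against 0 to 0.21) and Slc22a28 in NMN 4 (78 against 56.69 to 57.8). The remaining high values were Slc2a1 in cisplatin 1 (71.49 against 58.56 to 60.06), Sprr2f in PBS 2 (0.16 against 0) and Ugt2b34 in cisplatin 1 (9.52 against 3.87 to 4.06). Below the other 3 lay Apaf1 in NMN 4 (2.11 against 4.08 to 4.54), Apoc3 in cisplatin 1 (175.9 against 323.2 to 350.4), Atp6v1b1 in NR 4 (51.39 against 61.52 to 63.11), Calcb in NR 1 (1.02 against 2.2 to 2.31), Ccl2 in NR 3 (2.66 against 2.96 to 3.01) and Cd79a in PBS 3 (0.17 against 0.39 to 0.41). Also low were Mavs in cisplatin 3 (28.23 against 36.4 to 38.29), Mt2 in PBS 1 (97.88 against 153.3 to 163.2), Slc22a8 in cisplatin 2 (5.24 against 6.49 to 6.72), Slc5a2 in cisplatin 4 (26.13 against 30.75 to 31.52) and Tef in cisplatin 3 (29.84 against 45.41 to 47.38).

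For 9 lists the effect of NMN differed from that of NR by camera with a preset correlation, as a difference of mean log2 values, NMN minus NR. It was -0.255 for p53 targets, -0.302 for tubular injury markers, -0.124 for ferroptosis and iron handling, -0.144 for NRF2 targets, -0.285 for complement and acute phase and -1.449 for adipose genes, and 0.098 for the proximal tubule, 0.086 for oxidative phosphorylation and 0.062 for the citric acid cycle. None of the 9 was called with an estimated correlation or by fry, and the exact permutation p of the list means was at least 0.143.

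As the way from PBS to cisplatin on the TPM scale, interferon-stimulated genes lay at 14.4% with NMN and 16.3% with NR and cytokines at 25.8% and 34.2%. Thick ascending limb genes lay at 34.9% and 50.2% and adipose genes at -2.8% and 53.3%. These are percentiles 0.4 and 0, 99.5 and 99.9, 99.6 and 100, and 0 and 100 of matched random lists, for lists picked after their values were seen. A further distance was taken from the median position, in the same library, of all genes changed at least 2-fold in the direction of the list's members. It therefore cannot tell whether lists keep to the straight line. Against the spread between libraries, 1 of 30 lists with NMN and 2 of 30 with NR lay more than 3 SE from that median. The lists were NRF2 targets (4.6 percentage points with NMN, SE 1.4, and 6.3 with NR, SE 1.3) and cytokines with NR (8.2, SE 1.3), each nearer to cisplatin. Interferon-stimulated genes lay -6.7 (SE 2.7) with NMN and -7.7 points (SE 2.8) with NR from that median, nearer to PBS. Cytokines with NMN lay 5.2 points (SE 1.8) from it. Thick ascending limb genes lay 17 (SE 11.7) and 17.5 (SE 10.5) and adipose genes -20.7 (SE 10.1) and 29.7 points (SE 31.2) from it. In a fit of each precursor library on the 4 PBS and 4 cisplatin libraries, the same-numbered PBS library took 60.1%, 82.7% and 60.3% of the PBS weight in NMN 1, 2 and 4 and 79.6% and 74% in NR 2 and 4, the largest part in each of these 5. It took 24.7% in NMN 3, 35.7% in NR 1 and 20.7% in NR 3 (95% intervals over 200 bootstraps of genes 18.9% to 30.6%, 27.1% to 45.4% and 14.5% to 27.5%), where an even split would give 25%.

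With NMN and NR the libraries lay 20.7% and 25.9% of the way from PBS to cisplatin on the TPM scale, and one mixing proportion for every gene was tested on the 3559 genes that cisplatin changed at least 2-fold. In both groups 0% of these genes left the straight line (limma, with 64 and 145 genes at an unadjusted p under 0.05). Simulated data with 200 of these genes moved off it recovered 74.5% and 77.5% of them at 2-fold but 25% and 30.5% at 1.5-fold. With fewer genes moved, the adjusted threshold would be stricter and recovery may be lower. Single genes therefore keep to a common proportion at that power at most, and whether every list keeps to it stays open. Under a common proportion, genes that rose and genes that fell would lie at the same position. They lay at 19.5% and 26.1% with NMN and at 23.8% and 34% with NR. Their ranges over the splits overlapped. The splits reuse the same libraries and each gave both positions, so this overlap is not a test of the gap. No test of the gap was run, and these positions do not decide it. Were carried-over cisplatin RNA the whole source of its position, NMN 1 would hold at least 46 TPM of adipose transcripts. NMN 3 and NR 1 would hold at least 61.1 TPM. NMN 1, NMN 3 and NR 1 held 30, 51.7 and 23.2 TPM, which argues against it as their whole source. A smaller carry-over is not excluded, and this bound has no error term. In NMN 3, NR 1 and NR 3 the interval for the same-numbered PBS library lay under 50% of the PBS weight. This argues against that library as the main source of their PBS part, but a smaller part is not excluded. These intervals come from resampled genes and do not hold the spread between libraries. Each account stays open for the other 5 libraries of its test. In 5 libraries the same-numbered PBS library held most of the PBS weight, which shared handling of same-numbered samples could also give. An injury of fewer tubules, or a lesser or later one in all of them, could give the same line and stays open as an untested biological explanation.

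Red blood cell transcripts were low in the cisplatin libraries, at a summed 19.4 ± 11.8 TPM against 2980 ± 871 with PBS, 2080 ± 624 with NMN and 1960 ± 554 with NR (log2 difference of cisplatin to PBS -7.33, SE 0.49). Less blood in the kidneys of the cisplatin group would lower platelet transcripts as well. Their summed TPM differed by 0.46 (SE 0.34) on the log2 scale, which met the bound set beforehand against less blood. That bound was wrong for these data, as only 2 of 12 platelet genes reached 1 TPM in PBS. Less blood therefore cannot be told apart from other reasons. A loss of young red blood cells that still hold globin mRNA may also lower these genes, and was not tested.

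More genes were called higher than lower with cisplatin (68.6% of 7693). After median-of-ratios scaling 50.5% were higher, but this scaling centres the median change (0.268 before and -0.001 after) and so gives a near-even split whatever the cause. A smaller share of the most abundant transcripts in the TPM total therefore cannot be told apart from a rise of most mRNAs. With the mitochondrially encoded genes removed 56.3% were higher, between the bounds set for this test, so that a smaller share of these transcripts alone cannot be told apart from either. A change in the total mRNA of the kidney was not tested, since TPM holds no absolute amount.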

How the results depend on the processing

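The fits without the 3 libraries of lowest weight and without NR libraries 3 and 4, and median-of-ratios scaling of the correlation of changes, were chosen after the data were seen. Counts of called genes stayed within 1.5 times the reported count in every alternative run except 3. For NMN against NR 1 gene was called instead of 0 with only the groups compared. For NR against PBS the count was 698 instead of 1296 without NR libraries 3 and 4, a fit that also has fewer libraries. For NMN against PBS it was 511 instead of 778 without NMN replicate 3. With each replicate left out in turn the counts ranged from 7197 to 7520 for cisplatin against PBS, from 5663 to 6196 for NMN and from 5430 to 5847 for NR against cisplatin, from 511 to 923 for NMN and from 981 to 1262 for NR against PBS, from 6330 to 6962 for the mean of NMN and NR, and 0 for NMN against NR. Over the other alternatives they ranged from 6302 to 8179, 5412 to 6556, 4784 to 6271, 542 to 884, 698 to 1533, 5758 to 7317, and 0 to 1. With an estimated correlation 1 list was called for cisplatin against PBS (27 reported), 2 each for NMN and NR against cisplatin, their mean and both against PBS (27, 25, 27, 21 and 24), and 0 for NMN against NR (9). In the same order fry called 34, 31, 31, 32, 13 and 16 lists in 1 direction and 41, 41, 40, 40, 23 and 26 in either direction, and 0 both ways for NMN against NR; fry does not set a list against other genes. The returned share under NR was 61.4% with the 500 genes of smallest p, against 67.1%, and under NMN 66.5% against 72.7%; over the scalings tried it was 66.1% to 67.1% and 71.6% to 72.4%. After median-of-ratios scaling the correlation of changes was -0.949 with NMN and -0.935 with NR. Of 672 results for 146 named genes 0 reversed; 473 of 520 calls held in every alternative and 29 of 152 results without a call gained 1 in at least 1. The causes of these differences were not tested. For the fit without NR libraries 3 and 4, fewer libraries cannot be told apart from the loss of those with adipose transcripts. With the replicate number as a block, 7839 genes were called for cisplatin against PBS and 6507 for NMN against cisplatin. Deviations from the group means correlated between same-numbered libraries of PBS, NMN and NR (best with the own number in 21 of 24 comparisons, against 8 of 24 with cisplatin). This hint of shared handling did not meet the rule for pairing, a correlation over 0.1 in each same-numbered pair. Of 4 pairs, 3 passed for PBS with NMN, 2 for PBS with NR and 3 for NMN with NR. Whether the cisplatin samples were handled apart is not given. Such handling could not be told apart from cisplatin in comparisons with that group. DESeq2 and edgeR were not run, since TPM are not counts, and the depth behind the values is unknown.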

Other observations

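Of the tests in this part, only that for genes beyond both PBS and cisplatin was chosen after the result was seen. Of all 12960 tested genes 5278 rose with cisplatin and 2415 fell, and lists of cell death, DNA repair, matrix and complement are given beside these counts. Of 22 genes of apoptosis, necroptosis and pyroptosis 12 rose and 2 fell (10 and 3 after median-of-ratios scaling). The TNF receptor gene Tnfrsf1a went from 23.8 ± 2.95 to 87.4 ± 5.65 TPM, and Bak1 and Apaf1 rose as well, while camera did not call the list (adjusted p = 0.0538). Of 16 genes of ferroptosis and iron handling 10 rose, led by Hmox1, Cp and Acsl4, and 1 fell (9 and 3 after median-of-ratios scaling; adjusted p = 0.0254, and 0.279 with an estimated correlation). Of 21 DNA repair genes 9 rose (8 when adjusted over the list alone; 7 rose and 2 fell after median-of-ratios scaling), and the list was not called (adjusted p = 0.196). Ercc1 went from 9.25 ± 3.42 to 287 ± 72.1 TPM and Ercc5 from 6.27 ± 1.49 to 24.2 ± 0.959 TPM. In the list of fibrosis and extracellular matrix 9 of 22 genes rose, among them Col18a1 and Timp1, and 7 fell (8 fell when adjusted over the list alone; 7 rose and 9 fell after median-of-ratios scaling). Its median change was -0.17 from that of all genes, its mean was 0.49, and it was not called (adjusted p = 0.939). Of 17 genes of complement and the acute phase 10 rose and 5 fell, with C3 at 4.12 ± 2.51 and 108 ± 15 TPM and Cfb at 226 ± 28.4 and 108 ± 9.82 TPM (adjusted p = 0.447 for the list). Of 10 histone genes that depend on replication, a list fixed as a sign of RNA quality, 5 rose and 1 fell (adjusted p = 0.744).

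Lists of metabolism and of the circadian clock went both ways. Of 16 genes of cisplatin transport and detoxification 9 fell, among them the dipeptidase gene Dpep1 (90.6 ± 9.1 to 4.38 ± 1.59 TPM) and the exporter gene Slc47a1, and 4 rose, among them Mt2 and Mt1 (358 ± 52.5 to 5816 ± 883 TPM). This list was called lower with cisplatin (camera adjusted p = 0.0079, and 0.255 with an estimated correlation). With NMN 8 of its genes rose over cisplatin alone and 4 fell, and with NR 9 rose and 5 fell (adjusted p = 0.00208 and 0.000903; 0.227 and 0.193 with an estimated correlation). Of 16 glycolysis genes 9 rose and 2 fell (10 rose when adjusted over the list alone; 7 rose and 5 fell after median-of-ratios scaling), with the glucose transporter gene Slc2a1 at 10.4 ± 1.66 and 62.2 ± 6.22 TPM (adjusted p = 0.335 for the list). Of 21 genes of cholesterol synthesis 8 fell, among them Hmgcs1 and Cyp51, and 3 rose, among them Msmo1 (adjusted p = 0.0309, and 0.488 with an estimated correlation). Of 19 genes of mitochondrial biogenesis 3 rose and 4 fell (2 rose when adjusted over the list alone; 1 rose and 9 fell after median-of-ratios scaling), with Ppargc1a at 5.5 ± 1.07 and 2.61 ± 0.43 TPM (adjusted p = 0.27 for the list). Of 16 clock genes 8 rose and 7 fell (8 fell when adjusted over the list alone; adjusted p = 0.189), with the output gene Dbp at 166 ± 34 and 21.2 ± 2.84 TPM and lower values of Hlf, Nr1d2 and Tef. Of 11 heat shock genes, fixed as a sign of sample handling, Hspb1, Hsp90aa1 and 1 other rose and Hspd1, Hspa8 and 1 other fell (3 rose and 6 fell after median-of-ratios scaling; adjusted p = 0.435). Among the tissues that could be carried along, 3 of 6 liver genes rose, among them Fgb and Apoc3, and 2 fell, among them Ttr (adjusted p = 0.744). Only 1 gene each passed the filter on low values for the adrenal gland (Star, adjusted p = 0.199), the pancreas (Cela1, which fell from 240 ± 35.2 to 39.2 ± 15.3 TPM) and skeletal muscle (Mylpf, adjusted p = 0.336). Of 4 tested genes of the sex chromosomes 1, Uty, fell.

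A few genes were called above both PBS and cisplatin: 2 with NMN, Cyp4a14 and Scg5, and 8 with NR, among them Cyp4a14, Cyp4a10, Acsf2, Ago3, B3gnt8, Gsta2 and Ugt2b34, all named after their values were seen. When a single library was left out, at least 1 of the 2 calls behind each ended for Cyp4a14 and Scg5 with NMN and for Acsf2, Ago3, B3gnt8, Cyp4a10 and Ugt2b34 with NR (highest adjusted p from 0.0818 to 0.14). Simulated mixtures of PBS and cisplatin libraries gave up to 20 and 18 such genes, so these counts do not exclude one mixing proportion. Cyp4a14 measured 18.1 ± 5.74 TPM with PBS, 18.4 ± 5.68 with cisplatin, 38.8 ± 8.05 with NMN and 62.3 ± 21.6 with NR. Higher activity of PPAR alpha, the factor that drives Cyp4a10 and Cyp4a14, is a candidate explanation that was tested on 22 other targets. Of these 22, 11 lay above the line between PBS and cisplatin with NMN and 13 with NR. The median distance of all 22 from the line was 0.003 with NMN and 0.066 with NR on the log2 scale, against -0.031 and -0.049 in matched lists. These medians lay at percentiles 91.1 and 100 of 10000 matched gene lists. The test set beforehand asked for both to lie above the higher bound. NR did, whereas NMN lay between the bounds and cannot be told apart from the spread of matched lists. A rise of these targets with both precursors therefore stays open, and these genes may have changed for other reasons.

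Other splits of the same libraries were fitted to ask whether the counts of called genes could arise from an arbitrary grouping. With the 2 groups compared and their 35 splits, cisplatin against PBS gave 7247 genes, NMN against cisplatin 6133 and NR against cisplatin 5826. The highest of the other splits gave 1. In each comparison the real split was the only 1 of 35 as large, which is the smallest share that 35 splits can give. The splits do not tell whether the libraries are separate animals. NMN and NR against PBS gave 594 and 1164 genes, where the highest other split gave 2, and the real split was again the only 1 of 35 as large. For the mean of NMN and NR against cisplatin (7181 genes) 1 of 100 splits, the real one, was as large, and the highest other gave 89 genes. For NMN against NR the 2 groups alone gave 1 gene, and 4 of 35 splits gave as many, so chance cannot be excluded. The highest other split, which set the libraries numbered 1 and 4 against those numbered 2 and 3, gave 14 genes. As 1 split of 35, picked as the highest, it does not by itself show a structure of the samples that follows their numbers. Outside cisplatin, the second principal component and the mitochondrially encoded share were also higher in libraries 1 and 4 than in 2 and 3. The share was 34.03% and 29.73% against 25.03% and 25.64% with PBS, and 28.35% and 27.89% against 25.02% and 22.74% with NMN. With NR it was 30.31% and 28.12% against 24.92% and 22.11%. In the cisplatin libraries it was 15.57% and 16.56% against 16.59% and 17.64%. Such a structure stays open, and its cause was not tested.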
